A study of Mus musculus with 19 samples.

How the data were processed

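The series comprised 19 samples, of which 17 were RNA-seq libraries of mouse morulae and E6.5 extra-embryonic ectoderm (ExE). The 2 CUT&RUN samples were not analysed here. Groups were taken from the labels: 2 control and 2 maternal knockout (matKO) morula libraries, and 2 control female, 2 control male, 4 matKO female and 5 matKO male ExE libraries. Per the labels, libraries were made with an ultra-low-input cDNA kit and a transposase-based library kit. The submitters' processing notes list HISAT2 2.1.0 and Cufflinks 2.2.1 with the mm9 build, without saying which step each served, and for CUT&RUN Trim Galore 0.4.5, Bowtie2 2.2.9, MACS2 2.2.1 and deepTools 3.0.2. How reads were assigned to alleles is not stated.

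The authors deposited RPKM for all genes in each library (22521 genes listed, 943 of them X-linked). Allelic RPKM per parental allele and library were also deposited by the authors. Deposited allelic counts are whole reads over sequence variants per gene and allele, with a median of 6 variants per gene in morulae and 8 in ExE. The authors' deposited tables of changed genes give a log2 ratio that equals, within 0.001, that of group mean RPKM after adding 0.1 to each mean (448 of 448, 154 of 154 and 399 of 399 genes found), and these were used only for counts of listed genes. In all, 21 per-sample columns were not used here. Symbols that a spreadsheet had turned into dates (25) were kept as listed. The 13 Y-linked genes listed had no value above 0 in any ExE library. Coordinates are those in the deposited tables and cover part of each gene.

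Allelic totals were 3327373 to 5109159 reads in morulae and 4696355 to 9828943 in ExE. The autosomal maternal percentage was 50.4 to 50.8 in morula counts and 47.2 to 48.1 in ExE allelic RPKM. Shares of single libraries are given with 95% Wilson intervals. For total RPKM the read depth is unknown.

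Column names were checked by matching each allelic column with the total RPKM of every library over genes with at least 50 mean reads per allele. All 4 morula count columns and all 13 ExE allelic RPKM columns matched best with the library of their own name. Of the 13 ExE count columns only 3 did, 10 matched another library, and all 13 matched a library of their own genotype. The plan assumed edgeR on ExE counts for each sex. Since the sexes were mixed in the count columns, the female and male comparisons, X-linked shares and list shares in ExE used limma or means on allelic RPKM instead. The sex-averaged allelic comparison kept edgeR on counts, with the sex names of the columns in the model, and a genotype-only model was added.

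Total expression was compared with limma 3.58.1 (trend, R 4.3.3) on log2(RPKM + 1) for genes with a mean of at least 1 RPKM in the stage, and the Benjamini-Hochberg adjusted p had to be under 0.05. ExE groups were fitted together, with contrasts in females, in males, averaged and between the sexes. Allelic counts were tested with edgeR 4.0.16 quasi-likelihood with library as a block and an allele by group term, for genes with a mean of at least 20 allelic reads. Allelic RPKM were tested with limma on the log2 ratio of maternal to paternal values after adding 1. DESeq2 1.42.0 served as an alternative. Shares of lists were means over genes with at least 10 reads in every library, and shares of the X and the autosomes were taken from the summed allelic signal. Both were compared by exact two-sided permutation within sex. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these and for figures.

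Gene lists (24 in ExE and morulae besides all X-linked genes) covered H3K27me3-dependent imprints and candidates, canonical imprints, X inactivation and escape, Polycomb complexes and targets, embryonic and trophoblast lineages, decidua, oocyte, 2-cell stage, p53, hypoxia, ribosomal and housekeeping genes, and Y-linked genes. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Genes with control bias had at least 75% of reads from the same parent in every control library, and were compared with Fisher's exact test.

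Named genes followed a fixed rule: Eed, Xist, Tsix and the core list, up to 8 called genes each way whose groups did not overlap, up to 4 called members per list, up to 20 by smallest p where few were called, and up to 10 allelic calls each way with at least 20 reads. Exceptions, such as markers of matKO males 4 and 5, members passing adjusted over a list alone and genes named for X-linked output, were chosen after their values were seen. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives covered pseudocount 0.1, no filter or a stricter filter (5 RPKM or 50 reads), quantile and median scaling, no trend, TMM, DESeq2, a replicate block, and leaving out each library. Same-number morula libraries correlated after removing group means (r = 0.702) but there were only 2 pairs, and in ExE the median was -0.019, so no pairing was used.

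The steps were tested on simulated data with 200 changed genes. In ExE with sex averaged, total log2 changes of 1 were recovered in 98% of genes with 2.48% false calls, and allelic log2 changes of 1 in 74% with 6.81% false calls. In morulae false calls were 8.82% for total and 8.46% for allelic changes. Real total changes in ExE may be harder to find than simulated ones. With sex averaged, Klhl13 (log2 change -2.38, limma adjusted p = 0.123), Cited1 (-1.47, 0.102) and Pir (-1.42, 0.104) did not pass. Called genes with an estimate of at least 2-fold numbered 3. The recovery in simulated data therefore does not show that other 2-fold changes were absent in ExE. Other splits of the ExE libraries were drawn within sex (100 of 315). For allelic counts these followed the sex names of the columns, so the splits were repeated with limma on allelic RPKM, a setting added after the data were seen.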

Results

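RNA-seq was collected from mouse morulae and from extra-embryonic ectoderm (ExE), the trophoblast tissue next to the epiblast, at embryonic day 6.5. Control embryos came from Eed-fl/fl mothers and maternal knockout (matKO) embryos from Eed-fl/fl mothers carrying Gdf9-Cre, which deletes the floxed gene in growing oocytes. All fathers were wild type and of the PWK strain, so that maternal B6/129 and paternal PWK transcripts could be told apart at sequence variants. The set held 2 control and 2 matKO morula libraries, and in ExE 2 control female, 2 control male, 4 matKO female and 5 matKO male libraries. The allele-specific tables held 3327373 to 5109159 reads per morula library over 10723 genes and 4696355 to 9828943 reads per ExE library over 9804 genes. The median gene had 51 to 80 allelic reads per library in morulae and 116 to 241 in ExE. Total expression was given as RPKM for 22521 genes. The labels do not say that each library came from a separate embryo or litter, so p-values measure only the spread between these libraries. A reciprocal cross was not analysed here, so a parental effect cannot be separated from a strain effect at a single gene except through the change between control and matKO.

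Eed, the Polycomb repressive complex 2 subunit that was deleted, was examined first (chromosome 7, 97103164 to 97103573 in mm9, the part of the gene that the tables give). In ExE its maternal allele supplied 45.8% ± 1.68 of the allelic RPKM in controls (SD, n = 4, range 43.9 to 47.7) and 13.7% ± 2.27 in matKO libraries (n = 9, range 11.1 to 17.1). Maternal Eed fell from 68.8 ± 6.67 to 14.2 ± 3.93 RPKM, while the paternal allele stood at 81.2 ± 5.64 in controls and 88.2 ± 17.9 in matKO libraries. The change of allelic share was a log2 ratio of -2.39 in the ExE read counts (edgeR adjusted p = 1.90e-08). In morulae the maternal share of Eed was 37.7% (95% Wilson interval 33.6 to 41.9) and 46.0% (40.6 to 51.4) in the control libraries, and 16.02% (12.5 to 20.3) and 20.9% (17.3 to 25.2) in the matKO libraries. That morula change did not pass the test (log2 ratio -1.65, edgeR adjusted p = 0.395). Intervals of this kind cover counting error only. Total Eed in ExE was 36.4 RPKM lower in matKO libraries with sex held fixed (exact two-sided permutation p = 0.0127 over 315 arrangements within sex), but its log2 change of -0.48 did not pass across all genes (limma adjusted p = 0.216). All 17 libraries carried the Eed allelic share of their genotype label.

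To ask whether genes silenced on the maternal allele by H3K27me3 in control embryos lost that silencing, maternal shares were compared in morulae. Gab1, an adaptor of receptor tyrosine kinase signalling (chromosome 8, 83288333 to 83290386), went from a maternal share of 4.92% ± 1.58 (n = 2) to 45.4% ± 1.91 (n = 2). Bbx, a gene with an HMG-box (chromosome 16, 50191957 to 50197759), went from 12.01% ± 1.76 to 54.5% ± 2.47. These were the 2 genes of 7872 that passed, both toward the maternal allele (edgeR log2 ratio 3.97, adjusted p = 0.00678, and 3.14, adjusted p = 0.0104), with 314 genes at an unadjusted p under 0.05. The count was 14 with DESeq2, 43 with replicate number as a block and 0 with limma on allelic RPKM. It depended on single libraries, being 123 without control 1, 51 without control 2 and 0 without matKO 1 or without matKO 2, where Gab1 and Bbx were lost as well. Sfmbt2, a Polycomb-related gene needed in trophoblast, had 0 maternal reads of 55 and of 100 in the controls, with upper Wilson limits of 6.53% and 3.70%, and 41.1% ± 15.7 in matKO morulae (edgeR adjusted p = 0.344). Sall1 likewise had 0 maternal reads in controls and 47.9% ± 20.6 in matKO morulae (edgeR adjusted p = 0.613). Ly6a stood at 6.53% ± 3.63 and 36.8% ± 0.263 (edgeR adjusted p = 0.0721). In data simulated for this comparison, changes of 1, 2, 3 and 4 log2 units were recovered in 14%, 56%, 80% and 88% of changed genes.

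The 5 measured members of a fixed list of genes with H3K27me3-dependent imprints (Gab1, Phf17, Sfmbt2, Slc38a4 and Smoc1) had a mean maternal share of 4.95% and 10.5% in the control morulae and 47.9% and 40.4% in the matKO morulae, a difference of 36.5 percentage points. All 5 lay at or below 25% in controls and between 25% and 75% in matKO morulae, with Slc38a4, an amino acid transporter, at 1.10% ± 1.55 and 30.7% ± 16.1 and Phf17 at 15.1% ± 10.6 and 45.4% ± 2.06. In a second list of genes named as candidates for this class, 9 of the 12 measured members lay at or below 25% in controls and 8 of those 9 moved between 25% and 75%, among them E2f3 (5.61% and 31.0%) and Sox21 (4.35% and 42.1%). By more than 10 percentage points, 9 of the 12 rose and 2 fell, Sri and E130012A19Rik (45.6% and 33.0%). The candidate list mean was 19.7% ± 1.34 in controls and 38.5% ± 5.55 in matKO morulae. Genes with DNA methylation-dependent imprints were compared in the same way. The paternally expressed ones, such as Peg3 and Snrpn, had mean maternal shares of 7.96% ± 0.0631 and 11.5% ± 1.15 over 10 genes, and the maternally expressed ones 54.1% ± 1.23 and 56.7% ± 2.01 over 12 genes. Of these 12 genes only 1 lay at or above 75% in control morulae and 1 at or below 25%, so their list cannot show a loss of imprinting here. Its mean also hides 2 genes that rose and 3 that fell by more than 10 percentage points. With 2 against 2 libraries the smallest exact two-sided permutation p is 0.333, which the 4 lists all gave, so none of these differences could pass.

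**Figure D1:**
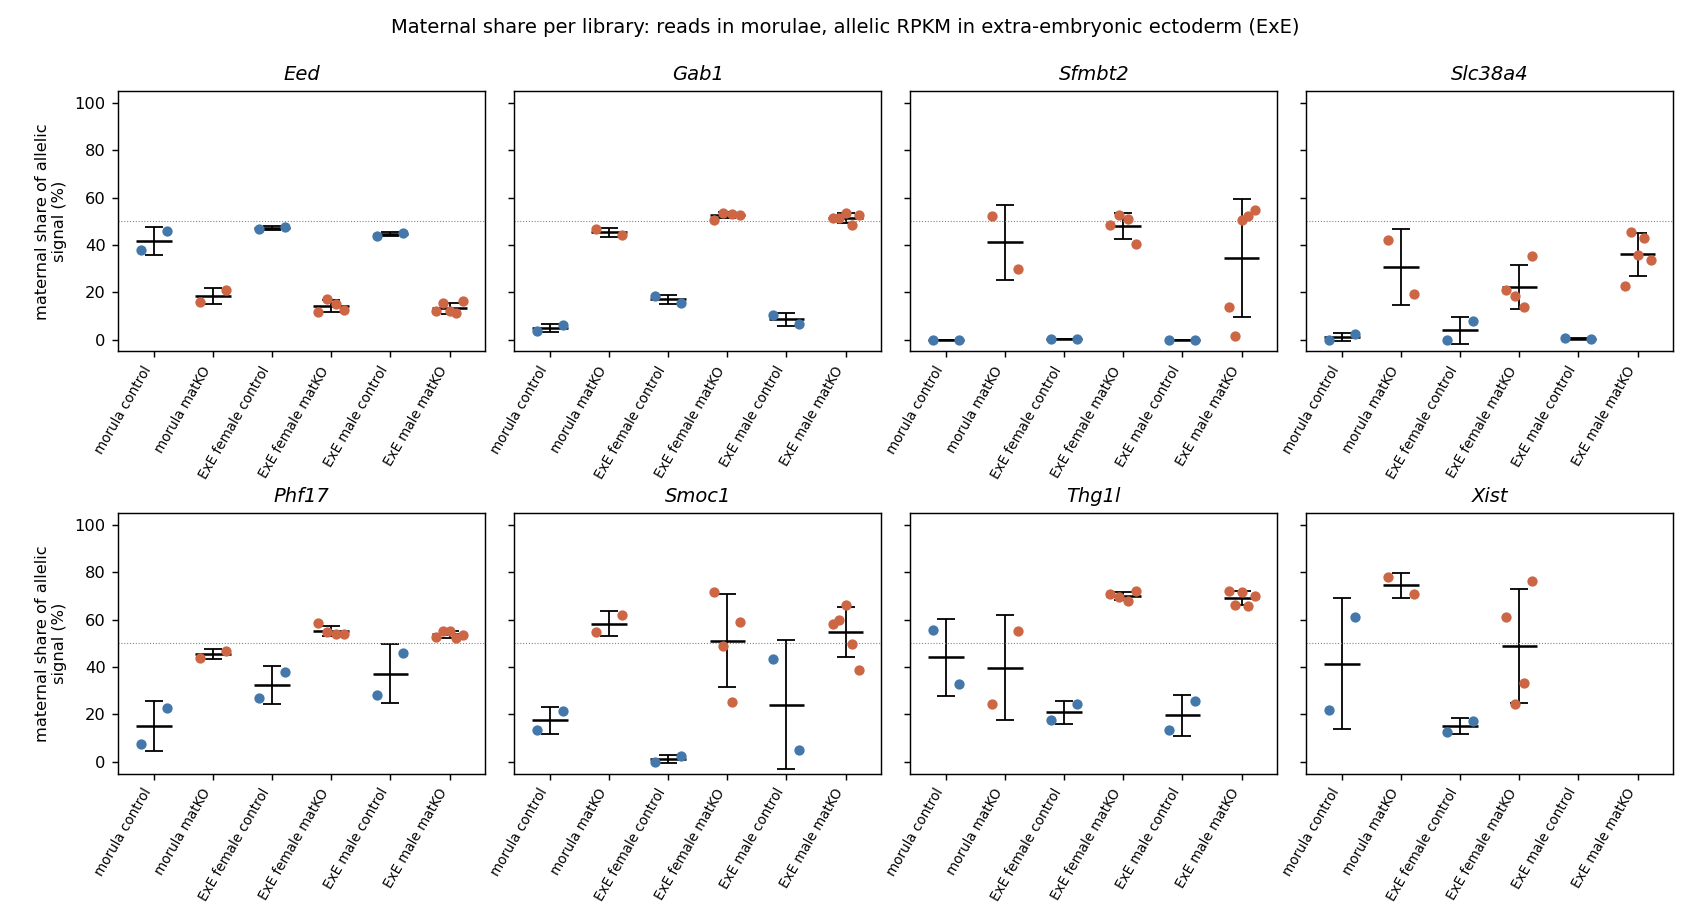
Maternal share of the allelic signal (percent, vertical axis) of 8 genes in each library of the control (blue) and maternal knockout (matKO, orange) groups named on the horizontal axis, from reads in morulae and allelic RPKM in ExE; points are libraries, lines are group means and bars are SD, the dotted line marks 50%, and male ExE is left out for Xist. Gab1 lay between 6.65% and 18.3% in ExE controls and between 48.3% and 53.5% in ExE matKO libraries, while Sfmbt2 was at 1.62% and 13.8% in 2 of the 9 matKO libraries.

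In ExE the 5 core genes again had higher mean maternal shares after maternal deletion of Eed. Only 4 of the 5 lay at or below 25% in controls. By allelic RPKM, Gab1 went from 12.8% ± 5.21 maternal (n = 4) to 51.9% ± 1.72 (n = 9), Slc38a4 from 2.17% ± 3.82 to 29.9% ± 11.3, Phf17 from 34.7% ± 8.95 to 54.4% ± 1.82 and Smoc1, a secreted calcium-binding protein, from 12.6% ± 20.6 to 53.02% ± 14.3. Sfmbt2 went from 0.128% ± 0.102 to 40.6% ± 19.3, with matKO male 1 at 13.8% and matKO male 2 at 1.62% although their Gab1 shares were 51.3% in both. The core list mean was 12.5% ± 3.11 in controls (range 9.08 to 16.5) and 46.0% ± 4.55 in matKO libraries (39.3 to 52.3), a difference of 33.4 percentage points and the smallest exact two-sided permutation p that 315 arrangements within sex allow (p = 0.00317, adjusted over the 4 lists 0.0127). Within females the difference was 34.8 points (exact p = 0.0667, the smallest possible) and within males 32.1 points (exact p = 0.0476, the smallest possible). The candidate list did not differ in ExE, at 47.1% ± 0.548 and 47.7% ± 1.11 over 11 genes (difference 0.643 points, exact p = 0.302, adjusted 0.321), and Bbx stood at 40.3% ± 3.62 and 43.8% ± 7.04. Of these 11 genes only 1 lay at or below 25% in ExE controls and 1 at or above 75%. The candidate list mean therefore cannot show a loss of maternal silencing here. The 13 paternally expressed genes with DNA methylation imprints had 10.7% ± 1.38 and 14.9% ± 6.60 (difference 4.06 points, exact p = 0.321, adjusted 0.321). MatKO male 4 (25.6%), male 5 (24.9%) and female 1 (19.5%) stood above all controls (9.13% to 12.3%), and the other matKO libraries had 8.81% to 12.4%. For the 18 maternally expressed ones the shares were 84.5% ± 0.711 and 82.5% ± 1.85 (difference -2.05 points, exact p = 0.0603, adjusted 0.121).

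Across all autosomal genes in ExE, 15 of 8152 changed their allelic share with sex averaged (edgeR adjusted p under 0.05), 13 toward the maternal and 2 toward the paternal allele, with 513 at an unadjusted p under 0.05. Besides Eed they included all 5 core genes, with adjusted p-values from edgeR of 2.63e-07 for Gab1, 0.00239 for Sfmbt2, Slc38a4 and Phf17, and 0.0408 for Smoc1. Thg1l, which encodes the tRNA-histidine guanylyltransferase (chromosome 11, 45761656 to 45761830), showed the largest shift of the 15 in percentage points, from 20.4% ± 5.47 to 70.6% ± 2.58 of reads (log2 ratio 3.28, edgeR adjusted p = 1.90e-08). Its maternal allele stood at 23.3 ± 5.20 RPKM in controls and 212 ± 24.6 in matKO libraries, and its paternal allele at 94.5 ± 18.7 and 92.8 ± 9.46. Sall1, a zinc finger regulator, went from 5.10% ± 7.25 to 44.7% ± 7.91, the snoRNA host gene Gas5 from 37.1% ± 6.30 to 48.8% ± 2.55, and Tmem50b fell from 41.4% ± 2.08 to 34.5% ± 2.95 (edgeR adjusted p = 0.00667, 0.0201 and 0.00841). The others were Fam36a, Glrx2, 2010002N04Rik, Wsb1 and Atpbd4, and each of these, with Sall1, Gas5 and Tmem50b, was lost without at least 1 of the count columns. Eed, Gab1, Phf17, Sfmbt2, Slc38a4 and Thg1l passed in all 21 other settings, whereas Smoc1 passed in 8, with an edgeR adjusted p of 0.532 without the column named control female 1. Sall1 was lost without the columns named control female 1 (0.0579) or control male 2 (0.0684), and Gas5 without control female 2 (0.0617) or control male 2 (0.236). Tmem50b was lost without control female 2 (0.0593) or control male 2 (0.0764), and Fam36a without control male 1 (0.149) or 2 (0.0748). The count was 7 without the column named control male 2 and 24 without that named matKO female 4, and 27 with DESeq2. Because the read-count columns do not carry the sex and replicate of their names, a fit with genotype alone was added after the data were seen, and it called 9 genes.

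Within each sex Gab1, Thg1l, Eed and Slc38a4 changed their share of allelic RPKM. In males 7 of 8139 autosomal genes passed (limma), namely Gab1 (8.62% ± 2.79 to 51.4% ± 2.01, adjusted p = 9.80e-08), Thg1l (19.6% ± 8.74 to 69.2% ± 3.06, 3.70e-05), Eed (44.5% ± 0.891 to 13.4% ± 2.32, 3.70e-05), Fam36a, Slc38a4 (0.397% ± 0.186 to 36.1% ± 9.01, 0.00941), 2410003L11Rik and Tmem80. The last 2 were not among the 15 genes of the sex-averaged test. At an unadjusted p under 0.05 there were 583 genes. The core genes Sfmbt2 (0.0413% ± 0.00770 to 34.6% ± 24.9, adjusted p = 0.240), Phf17 (37.1% ± 12.5 to 53.8% ± 1.43, 0.3995) and Smoc1 (24.1% ± 27.3 to 54.6% ± 10.6, 0.649) did not pass in males with limma. DESeq2 called 15. The limma call of Slc38a4 was lost without control male 1 (adjusted p = 0.136) or control male 2 (0.155), that of 2410003L11Rik without control male 2 (0.237), and that of Tmem80 without either of these controls or matKO male 2, 4 or 5 (0.0523 to 0.496). In females 15 autosomal genes passed, 10 toward the maternal and 5 toward the paternal allele, and the former included Gab1 (16.996% ± 1.89 to 52.5% ± 1.28, limma adjusted p = 2.30e-05), Thg1l (20.8% ± 4.79 to 70.0% ± 1.84, 1.27e-04), Sfmbt2, Phf17, Smoc1 and Slc38a4. Eed went from 47.2% ± 0.822 to 14.2% ± 2.48 (limma adjusted p = 1.27e-04). Without control female 1 Sfmbt2, Phf17, Smoc1 and Slc38a4 were lost (limma adjusted p = 0.204, 0.329, 0.298 and 0.609). Sfmbt2 and Smoc1 were lost without control female 2 (0.134 and 0.131). Phf17, Smoc1 and Slc38a4 were lost without matKO female 1 (0.0588, 0.0616 and 0.12), and Slc38a4 without matKO female 2 (0.0673) or 4 (0.106). A test of whether the genotype effect on allelic share differed between the sexes called 0 of 8139 autosomal genes with limma, with 332 at an unadjusted p under 0.05.

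To examine X inactivation, which silences the paternal X in extra-embryonic tissues of the mouse, the maternal share of X-linked allelic RPKM was computed per library without Xist and Tsix. In ExE it was 92.2% and 91.6% in the control females and 49.1%, 75.5%, 76.5% and 34.4% in matKO females 1 to 4 (91.9% ± 0.469 against 58.8% ± 20.7). All 4 matKO females lay below both controls, a difference of -33.1 percentage points (exact two-sided permutation p = 0.133 over 15 arrangements, the smallest possible being 0.0667), so this design could not reach 0.05. Males, which carry no paternal X, had 99.7% to 99.9%. In morulae, whose libraries have no sex label, the share was 65.9% and 86.4% in controls and 67.7% and 66.3% in matKO libraries (exact p = 1). The share of Xist, the RNA that coats the inactive X, ran the other way, at 14.9% ± 3.41 maternal in control females and 61.1%, 24.2%, 33.4% and 76.3% in matKO females 1 to 4 (limma adjusted p = 0.190). MatKO females 4 and 1, with the highest maternal Xist shares, had the lowest maternal shares of the other X-linked genes. Total Xist was 8.80 ± 1.30 RPKM in control and 8.27 ± 2.56 in matKO females, and 0.808 ± 0.236 and 0.824 ± 0.228 in males. The tables hold no strand information for reads, so Xist and its antisense partner Tsix cannot be told apart where they overlap, and the same holds for Kcnq1ot1 and Kcnq1 and for Airn and Igf2r.

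**Figure D2:**
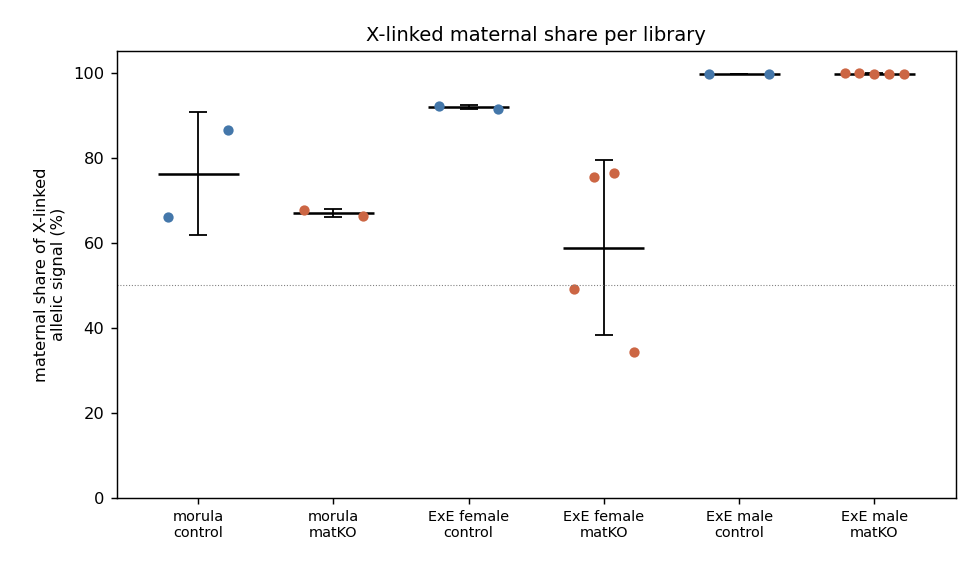
Maternal share of X-linked allelic signal (percent, vertical axis) in each library of the groups named on the horizontal axis, without Xist and Tsix, from reads in morulae and allelic RPKM in ExE; points are libraries, blue for control and orange for maternal knockout (matKO), lines are group means and bars are SD. The 4 matKO female ExE libraries lay between 34.4% and 76.5%, below the control females at 91.6% and 92.2%, and all males lay above 99%.

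Single X-linked genes moved toward the paternal allele in matKO females. Of 301 X-linked genes tested, 149 passed and all 149 went toward the paternal allele (limma on the log ratio of allelic RPKM, 164 calls among 8440 genes, 645 at an unadjusted p under 0.05). The fit pooled the spread of each gene with the male libraries, which carry no paternal X, while matKO females varied widely. These adjusted p-values are therefore likely too small. The genes also share a chromosome-wide shift in the same libraries, which gave an exact two-sided permutation p of 0.133. Rlim, an activator of Xist, went from 98.8% ± 0.862 to 59.98% ± 23.4 maternal (adjusted p = 0.00521), Hprt, of purine salvage, from 99.2% ± 0.885 to 67.7% ± 24.5 (0.00931), the placental gene Plac1 from 99.6% ± 0.514 to 53.4% ± 28.6 (0.0304) and Cited1, a transcriptional coregulator of trophoblast, from 99.8% ± 0.0399 to 78.6% ± 16.2 (0.00170). Ddx3x, which escapes inactivation, went from 89.8% ± 0.934 to 68.4% ± 13.9 (0.0447). Xlr3a, Xlr3b, Xlr4a, Rhox6 and Rhox9 belong to multicopy families and Pgk1 has processed copies, so their shares are uncertain. The number of calls was 22 without control female 1, 67 without control female 2 and 73 without matKO female 1. Rlim and Hprt were lost without control female 1, Plac1 without either control or matKO female 1 or 4, and Ddx3x without either control or matKO female 1. The read-count columns taken by name gave 4 calls with edgeR and 14 with DESeq2, settings that differ from limma on allelic RPKM in both the tool and the columns.

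Genes with a strong parental bias in every control library were counted as a wider measure. In morulae 350 autosomal genes had a paternal share of at least 75% in both controls, and 93 of them (26.6%) had a mean share between 25% and 75% in matKO morulae. Maternally biased genes served as a comparison for the return toward the middle that selection gives, though whether they respond themselves was not tested. For them the numbers were 71 of 356 (19.9%, two-sided Fisher's exact p = 0.0405). Genes of the same libraries are not independent replicates, so the Fisher p-values in this paragraph do not measure the spread between libraries. That difference depended on the settings, with 26 of 148 against 8 of 115 at a threshold of 90% (exact p = 0.0151) and 56 of 255 against 43 of 274 with at least 20 reads (exact p = 0.0743). Without control 1 the genes between 25% and 75% were 304 of the paternally biased (42.5%) and 324 of the maternally biased ones (42.02%, Fisher's exact p = 0.875). Without control 2 they were 405 of 795 and 351 of 783 (50.9% and 44.8%, exact p = 0.0156). The exact p was 0.138 without matKO 1 and 0.00973 without matKO 2. In ExE 13 of 162 paternally biased genes, among them Gab1, Sfmbt2 and Slc38a4, and 8 of 166 maternally biased ones lay between 25% and 75% in matKO libraries (exact p = 0.266). Leaving out matKO female 3 gave 15 against 6 (exact p = 0.0431), and leaving out control female 1 gave 25 of 181 against 25 of 196 (exact p = 0.764). Without control male 1, male 2 or female 2 the numbers were 20 of 181 against 15 of 185, 20 of 177 against 16 of 190 and 21 of 185 against 18 of 197 (exact p = 0.377, 0.384 and 0.503).

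Total expression was then compared between matKO and control morulae. Cox7b2 had 21.2 ± 6.08 RPKM in controls and 114 ± 10.5 in matKO morulae, the placental lactogen Prl3b1 169 ± 50.3 and 449 ± 80.9, and Pmaip1, a pro-apoptotic target of p53, 10.9 ± 8.32 and 43.0 ± 13.1 (log2 changes of 2.39, 1.42 and 2.05 on the log2(RPKM + 1) scale). Rlim stood at 19.1 ± 11.5 and 3.67 ± 2.33 RPKM (log2 change -2.07). Among the core genes Gab1 had 9.51 ± 1.79 and 17.9 ± 3.67 RPKM, Sfmbt2 3.17 ± 1.31 and 5.24 ± 0.923, and Xist had 30.9 ± 9.71 and 60.4 ± 18.2. None of these passed, and 0 of 10329 genes did (limma, lowest adjusted p = 0.296 for Rnu11, which was listed at 0 in both controls and at 18.1 ± 5.75 RPKM in matKO), with 92 genes at an unadjusted p under 0.05. Groups did not overlap for 1976 genes, fewer than the 33.3% that chance gives with 2 against 2. The count was 6 without control 1, 16 without control 2, 1 without matKO 1 and 2 without matKO 2. With replicate number as a block 164 genes passed with limma, 111 up and 53 down, against 2 with the pairs crossed. The first principal component (72.8% of variance) separated replicate 1 from replicate 2 in both genotypes, and 2 pairs cannot show whether the numbers pair the libraries. Simulated changes of 1, 1.5, 2 and 3 log2 units were recovered in 2%, 26%, 70% and 88% of genes. The simulation changed only genes with a mean log2 value above 2 and used independent noise, without the difference between replicates 1 and 2. Real changes may thus be harder to find, and Cox7b2, Rlim and Pmaip1 did not pass with estimates beyond 2 log2 units. The lack of calls therefore does not show that 4-fold changes were absent.

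Fixed gene lists were tested in morulae against all other genes. The 24 p53 targets had a median log2 change of 0.58 (Plk2 1.26, Ccng1 0.98) and stood above other genes (camera adjusted p = 1.99e-12, adjusted p = 0.886 with an estimated correlation). The imprint candidates (median 0.30, 20 genes, 6.86e-05 and 0.909 with an estimated correlation) and the core list (median 0.55, 5 genes, 0.00109 and 0.886 with an estimated correlation) stood above as well. Lists of epiblast (0.0322, and adjusted p = 0.886 with an estimated correlation) and hypoxia or glycolysis genes (0.0473, and adjusted p = 0.956 with an estimated correlation) did so more weakly. The 21 trophectoderm genes, which mark the outer cells of the blastocyst, had a median of -0.37 (camera adjusted p = 0.00859, adjusted p = 0.956 with an estimated correlation), and 239 of 347 X-linked genes lay below 0 with a median of -0.21 (1.03e-09, and adjusted p = 0.909 with an estimated correlation). Single libraries carried part of this, by medians with each library left out that were added after the data were seen. The trophectoderm list mean was 3.65 and 5.38 in controls and 3.77 and 4.56 in matKO morulae, and its median change was 0.58 without control 2. Without control 1 the median was -0.01 for X-linked genes, of which 177 lay below 0, and -0.10 for hypoxia or glycolysis genes. The medians of the other 4 lists stayed above 0. None of the 7 list results held with an estimated correlation, and 0 members of any list passed, overall or adjusted over the list alone. The other 17 lists did not pass with camera, at an adjusted p of 0.587 for maternally expressed imprinted genes, ribosomal proteins, PRC2, PRC1, developmental Polycomb targets, inner cell mass and trophoblast stem genes. It was 0.614 for oocyte genes, 0.616 for 2-cell stage genes and housekeeping genes and 0.719 for paternally expressed imprinted genes. Primitive endoderm had 0.784, ectoplacental cone 0.814 and visceral endoderm 0.841. The last lists had 0.898 for the X-inactivation centre, 0.977 for X escape genes and 0.98 for decidua and maternal blood.

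In ExE total expression, averaged over the sexes, Thg1l rose from 30.5 ± 1.86 and 25.7 ± 2.88 RPKM in control females and males (n = 2 each) to 77.5 ± 5.15 in matKO females (n = 4) and 75.3 ± 8.95 in matKO males (n = 5). Gab1 rose from 27.7 ± 4.45 and 23.3 ± 0.710 to 53.9 ± 4.801 and 55.4 ± 5.32 RPKM. Plaur, the urokinase receptor (chromosome 7, 25247519 to 25247586), rose from 75.9 ± 6.72 and 51.5 ± 3.76 to 115 ± 16.2 and 97.4 ± 5.41 RPKM, and the imprint candidate C430002E04Rik from 2.12 ± 0.961 and 1.84 ± 0.633 to 5.52 ± 1.14 and 5.63 ± 0.999. Pigp, of glycosylphosphatidylinositol synthesis (chromosome 16, 94580370 to 94580781), fell from 106 ± 4.91 and 120 ± 12.3 to 75.7 ± 6.23 and 69.2 ± 7.48 RPKM. These were the 5 of 9915 genes that passed with limma, at log2 changes of 1.41 (SE 0.09, adjusted p = 9.40e-06), 1.08 (1.10e-04), 0.74 (0.00471), 1.16 (0.0145) and -0.64 (0.0104), and 1592 genes were at an unadjusted p under 0.05. C430002E04Rik was lost without control female 1 (adjusted p = 0.0876) or control male 1 (0.202). By allelic RPKM its maternal share was 98.6% ± 1.74 in control and 98.0% ± 1.49 in matKO ExE. Its rise thus came from an allele already expressed in controls and was not a loss of maternal silencing in ExE. Pigp was lost without control female 1 (0.0598), control female 2 (0.0956) or control male 1 (0.155). Of the 5 genes, 3 were left without control female 1 or control male 1 and 4 without control female 2. The count was 17 without matKO female 2, and 14, 11 and 8 without matKO males 2, 4 and 5. Without both matKO males 4 and 5, a setting added after the data were seen, 69 genes passed, 32 up and 37 down, with the 5 among them.

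Most core genes whose maternal share changed did not pass in total expression. Sfmbt2 had a log2 change of 0.99 (limma adjusted p = 0.122), Smoc1 0.94 (0.124), Slc38a4 0.56 (0.104) and Phf17 0.33 (0.124), while Peg3, a paternally expressed gene, had -0.75 (0.0540) and Xist -0.05 (0.902). As a list, the 5 core genes rose (camera adjusted p = 3.53e-07, adjusted p = 0.0199 with an estimated correlation), and all 5 passed adjusted over the list alone against 1 over all genes. Their mean log2(RPKM + 1) was highest in matKO males 4 and 5, at 5.99 and 5.81 against 4.69 to 5.64 in the other ExE libraries. Of 22 p53 targets 8 rose adjusted over the list alone and 0 over all genes, among them Mdm2 (0.60), Sesn2 (0.53) and the cell cycle inhibitor Cdkn1a (0.88) (camera adjusted p = 1.37e-04, adjusted p = 0.375 with an estimated correlation). Of 25 hypoxia or glycolysis genes 4 rose adjusted over the list alone, the glycolytic enzymes Gpi1 (0.35), Ldha (0.30), Tpi1 (0.31) and Aldoa (0.29), and the oxygen sensor Egln3 fell (-0.72), with 0 over all genes (camera adjusted p = 3.78e-04, adjusted p = 0.375 with an estimated correlation). Aldoa, Ldha and Tpi1 were highest of all ExE libraries in matKO males 4 and 5. Of 17 paternally expressed imprinted genes 4 fell adjusted over the list alone, Peg3, Ndn (-0.58), Snrpn (-0.50) and Snurf (-0.43) (camera adjusted p = 0.00732, adjusted p = 0.129 with an estimated correlation), and Ndn and Peg3 were lowest in the same 2 libraries. Without these 2, a setting added after the data were seen, Peg3 passed over all genes (log2 change -0.65, limma adjusted p = 0.0186). The hypoxia or glycolysis list (camera adjusted p = 0.00201, adjusted p = 0.821 with an estimated correlation) and the paternally expressed list (0.01, adjusted p = 0.196 with an estimated correlation) still passed with the preset correlation. Snrpn and Snurf share a transcript.

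The remaining lists did not pass in ExE with camera. Adjusted over the list alone, single members did: Gnas (0.60) among 20 maternally expressed imprinted genes (camera adjusted p = 0.956), C430002E04Rik among 14 candidates (0.587), Lamb1 (-0.69) among 7 primitive endoderm genes (0.418), and Cited1 (-1.47) among 13 visceral endoderm (0.963) and 19 ectoplacental cone genes (0.299). No member passed among trophoblast stem genes (camera adjusted p = 0.956), trophectoderm (0.480), epiblast (0.537), inner cell mass (0.956), decidua and maternal blood (0.506), developmental Polycomb targets (0.462), PRC1 (0.956), PRC2 (0.506), ribosomal proteins (0.137), housekeeping genes (0.956), X escape genes (0.847) or the X-inactivation centre (0.956). Lists of oocyte and 2-cell stage genes were tested in morulae only, and 0 Y-linked list genes could be tested.

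Within females 2 genes passed, Thg1l (limma log2 change 1.31, SE 0.12, adjusted p = 0.00142) and Gab1 (0.94, 0.0250), with 452 at an unadjusted p under 0.05. Gab1 was lost without control female 2 (adjusted p = 0.472) or matKO female 2 (0.0614), 3 (0.0896) or 4 (0.121), leaving 1 call without matKO female 2, 3 or 4, and 3 genes passed without control female 1 or matKO female 1. Within males 4 passed, Thg1l (1.51, adjusted p = 1.94e-04), Gab1 (1.21, 0.00118), Plaur (0.91, 0.0188) and Pigp (-0.79, 0.0338), with 1456 at an unadjusted p under 0.05. Without control male 1 only Thg1l was left (1 call), with Gab1 at an adjusted p of 0.0711, and 2 calls each remained without control male 2 or matKO male 1. Plaur was lost without control male 1 (0.236), control male 2 (0.387) or matKO male 1 (0.0505). Pigp was lost without control male 1 (0.914), control male 2 (0.269) or matKO male 1 (0.0836), 2 (0.0941) or 5 (0.0533). The count was 6 without matKO male 3. Without matKO males 4 and 5 all 4 passed together with 4 more, among them Cdkn1a (log2 change 1.42) and Fosl1 (1.93), named after their values were seen. The core list rose in females (camera adjusted p = 1.26e-07, adjusted p = 0.0162 with an estimated correlation, 3 of 5 adjusted over the list alone) and in males (1.25e-05, adjusted p = 0.0441 with an estimated correlation, 4 of 5). The p53 list passed in females (2.70e-04, adjusted p = 0.499 with an estimated correlation) and in males (0.00280, adjusted p = 0.664 with an estimated correlation), where 7 rose adjusted over the list alone. The 2 genes called in both sexes compare with 6.05e-04 expected from independent lists. That number is likely too low, since both contrasts used the same estimated spread of each gene. Log2 changes of autosomal genes correlated across genes with Pearson's r = 0.393 and Spearman's rho = 0.397, genes not being independent replicates. No gene differed in its genotype effect between the sexes (0 of 9915 with limma, 170 at an unadjusted p under 0.05, lowest adjusted p = 0.99), and leaving out control female 1 or 2 gave 1.

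Output of the X chromosome was compared with that of the autosomes. In ExE 23 X-linked genes fell and 3 rose adjusted over the list of 359 alone, and 0 over all genes. Without matKO males 4 and 5, a setting added after the data were seen, 8 fell and 1 rose over all genes, among them Klhl13 and Spin2 (limma adjusted p = 0.0138 for both), Cited1 (0.0492) and Otud5 (0.0186). In all libraries those that fell included Klhl13, a substrate adaptor of a ubiquitin ligase (42.0 ± 4.56 and 54.0 ± 4.62 RPKM in control females and males, 11.4 ± 4.72 and 10.4 ± 9.24 in matKO), Cited1 (242 ± 3.29 and 265 ± 16.3 against 87.9 ± 39.8 and 110 ± 40.6) and Spin2, and those that rose were Otud5, Renbp and Idh3g. The X-linked list stood below other genes (camera adjusted p = 1.37e-04, adjusted p = 0.129 with an estimated correlation), with a median log2 change of -0.09 against 0.02 for autosomes. Per library, the X minus autosome difference of median log2 values was 0.34 lower in matKO ExE with sex held fixed (difference -0.34, exact two-sided permutation p = 0.00317, the smallest possible). The median log2 change per gene, X-linked minus autosomal, was smaller, at -0.10 averaged, -0.05 in females and -0.14 in males. The size of the shift thus depends on the measure. MatKO males 4 and 5 had the lowest per-library values (-0.63 and -0.54), and without them the per-library difference was -0.29 (exact p = 0.00667, the smallest possible). With all libraries it was -0.29 in females (exact p = 0.133), -0.39 in males (exact p = 0.0476, the smallest possible) and -0.33 in morulae (exact p = 0.667), where control 1 carried it (0.09, against -0.47 in control 2 and -0.45 and -0.58 in matKO) and the difference without it was -0.04. The X-linked list differed between the sexes with camera (adjusted p = 0.0278, adjusted p = 0.877 with an estimated correlation), and not without matKO males 4 and 5 (adjusted p = 0.174).

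Among the ExE libraries, matKO males 4 and 5 stood apart from the other 11 in several gene lists. Hand1, a regulator of trophoblast giant cells, was at 312 and 295 RPKM in these libraries and at 27.9 to 103 in the others, and the ectoplacental cone genes Gjb5 (730 and 488) and Ascl2 (362 and 208) were highest there too. Esrrb, a trophoblast stem cell factor, was at 0.310 and 3.77 RPKM against 26.0 to 55.8, Sox2 at 0.0717 and 1.501, and Bmp4 at 2.95 and 14.8. The mean log2(RPKM + 1) of the trophoblast stem list was 3.73 and 4.25 against 4.69 to 5.06, that of trophectoderm 5.76 and 5.96 against 4.87 to 5.47, and that of epiblast 2.70 and 3.18 against 3.45 to 4.60. The decidua and maternal blood list was also outside, at 3.22 and 3.34 against 1.77 to 2.54. Only 3 of its 29 genes could be tested, and these, Cd52, Cd68 and Cryab, were all highest in matKO males 4 and 5. The ectoplacental cone list mean was not outside, at 5.70 and 5.55 against 4.71 to 5.85, and its members Mmp9, Rhox6 and Rhox9 were lowest there. Genes listed above 0 numbered 13455 and 14496 against 14794 to 15785. Visceral endoderm genes were high in matKO male 5, with Spink3 at 121 RPKM against at most 14.4 in the other libraries and Apom at 62.9 against at most 6.98.

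**Figure D3:**
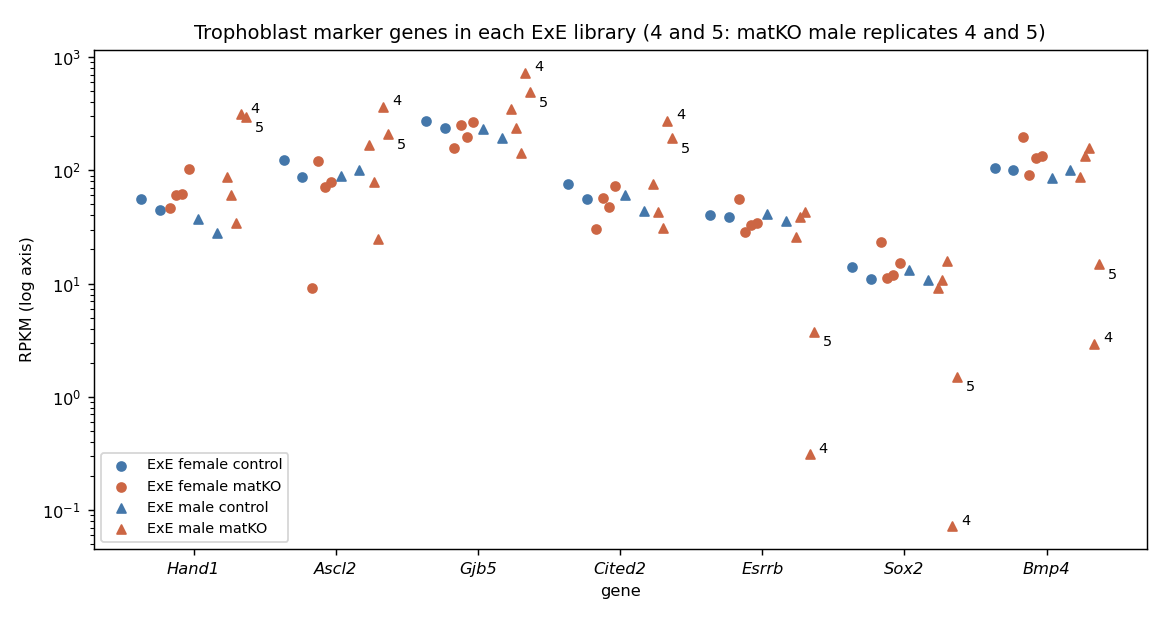
Expression (RPKM, logarithmic vertical axis) of 7 trophoblast marker genes (horizontal axis) in each ExE library, circles for females and triangles for males, blue for control and orange for maternal knockout (matKO); each point is a library. The points marked 4 and 5 are matKO males 4 and 5, in which Hand1 was at 312 and 295 RPKM against at most 103 elsewhere and Bmp4 at 2.95 and 14.8.

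The authors' deposited tables of changed genes hold 448 genes for morulae (178 raised, 270 lowered), 154 for ExE females (58 raised, 96 lowered) and 400 for ExE males (196 raised, 204 lowered). Their smallest absolute log2 ratio is 1, and the smallest mean RPKM of the higher group is 1.0007 to 1.014 over the 3 tables. Whether a test was also applied was not examined here. Of the genes in the authors' deposited tables that could be tested here, 0 of 358, 1 of 125 and 2 of 328 passed limma after adjustment, and 80, 62 and 205 had an unadjusted p under 0.05. X-linked genes made up 81, 31 and 49 entries of the authors' deposited tables, of which 59, 29 and 41 were lowered. For morulae the authors' deposited tables have 6 trophectoderm genes, all lowered, such as Krt8 (log2 ratio -1.59) and Eomes (-1.37), and 4 p53 targets, all raised. Of the ExE genes in the authors' deposited tables, 68 are listed for both sexes, Thg1l, Sfmbt2 and Klhl13 among them, and 59 of the 68 have the same direction in both.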

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

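The test of neighbours on chromosome 11 and the splits of allelic RPKM were set before their results were seen, and the other tests here were chosen after the results were seen. Of 81 groups of 4 to 10 libraries, 5 held a library far from the others, and chance gives about 1 in 20 groups, or 4. H19 was at 324 RPKM in matKO male 4, with the nearest matKO male at 192. Xist was at 12.1 RPKM in matKO female 1, with the nearest matKO female at 7.29. The mean maternal share of maternally expressed imprinted genes was 81.7% in matKO female 1 (nearest 83.0) and 77.9% in matKO male 4 (nearest 82.3). The mean log2(RPKM + 1) of those genes was 4.28 in matKO female 1 (nearest 4.64).

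In female ExE the maternal share of X-linked signal was lower in all 4 matKO than in both control libraries. The tables argue against wrong genotype labels, since the highest Eed maternal share of the 4 matKO females was 17.1% against at least 46.6% in control females. They argue against maternal tissue in the controls, since the autosomal maternal share of controls minus matKO was -0.218 percentage points, and against misassigned alleles, since the lowest X share of matKO males was 99.7%. A partial loss of imprinted X inactivation, with a variable choice of the inactive X in each library, may explain the pattern, but was not tested. To decide it, the allelic shares of single cells would have to show whether each cell expresses one X or both, and 2 controls cannot give an exact p under 0.05 for the pattern itself.

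Thg1l had a higher maternal share in matKO than in control ExE. Genes near Thg1l changed no more often than other autosomal genes (4 of 74 at an unadjusted p under 0.05, one-sided Fisher's exact p = 0.692). This gave no sign of a stretch of chromosome 11 of another strain origin. It cannot exclude such a stretch, which would change only those neighbours whose expression differs between the maternal strains. Control morulae had 55.4% and 32.6% and matKO morulae 24.2% and 55.3%, and the lack of a rise goes against loss of an imprint already acting in the morula. It cannot be told apart from other causes because the lower control's Wilson interval reaches 24.04% and libraries of the same genotype differed widely (SD 16.1 and 22.03). An imprint that acts only later, or a variant at the gene that differs between the mothers, could also give the pattern and was not tested.

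MatKO males 4 and 5 stood apart from the other ExE libraries. The 10 highest genes held 6.02% of RPKM in matKO male 4, above the 4.77% to 5.56% of the other 11, and 5.12% in matKO male 5. A few genes thus did not hold most of the RPKM in either library, but RPKM is scaled by gene length and does not give shares of reads. More ectoplacental cone cannot be told apart from other causes: 6 of 19 genes of its list were highest in both libraries, against 11.9% of all tested genes (one-sided Fisher's exact p = 0.0197), but 3 were lowest and the list mean lay within the range of the others. Trophectoderm genes were highest more often (12 of 21, one-sided Fisher's exact p = 8.33e-07), although 3 (Cdx2, Cldn6 and Eomes) were lowest. Only 3 of 29 decidua and maternal blood genes could be tested, and all 3 were highest (one-sided Fisher's exact p = 0.00170). The autosomal maternal share, which maternal tissue would raise, spanned only 50.4% to 50.9% over the ExE count columns. Both libraries were picked because they stood apart in the same values, genes of a list can move together, and the lists were not adjusted for. The Fisher p-values in this paragraph therefore do not measure chance. A change of trophoblast differentiation in these embryos stays open and was not tested.

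Other splits of the 13 ExE libraries within sex were drawn, 100 of 315 with the real split among them. For total expression 7 of the 100 splits called at least as many genes as the real 5, and the highest other split called 1086, so chance cannot be excluded for that count and a structure of the samples other than genotype is present. For allelic share 1 of the 100 splits, the real one with 15 genes, reached its count, and the highest other called 10, but the count columns do not carry the sex of their names, so these splits were not within sex. With limma on allelic RPKM, whose columns match their names, 1 of 100 splits, the real one with 9 genes, reached its count and the highest other called 6. The tables therefore argue against chance for the count from allelic RPKM, but 100 splits cannot exclude it. That count includes Eed, the deleted gene, whose maternal share falls by design.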

How the results depend on the processing

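Values that changed with a setting are given by setting, and the cause was not tested. Settings without matKO males 4 and 5, with genotype only, with crossed pairs, with limma on allelic RPKM in place of counts, or with count columns as named were added after the data were seen. Of 3032 values of 205 single-gene results 2541 stayed on the same side of the threshold, 276 weakened, 197 strengthened and 18 reversed. Of 318 values of 28 summary results 235 stayed and 77 moved.

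Without a filter 12 genes were called in females, 15 in males, 38 averaged, 1 between the sexes and 4 for morula allelic share. The averaged count was 10 with pseudocount 0.1, 11 with a mean of at least 5 RPKM, 11 without a trend, 13 with quantile scaling and 15 with median centring. With quantile scaling the log2 change of Slc38a4 in morulae was -0.0085 and that of Xist averaged 0.0015, and with median centring that of Xist in males was -0.011. A fit of the female groups alone gave 5 calls. Over the 14 other settings of the female comparison, Thg1l passed in 14 and Gab1 in 8.

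With a replicate block, total calls were 164 in morulae, 1 in females, 1 in males and 9 averaged, and allelic calls 43 in morulae and 64 in females, while Tsix in females had a log2 change of -0.012 and Xist in males -0.023. Crossed pairs in morulae gave 2 calls.

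Without matKO males 4 and 5 there were 8 calls in males and 69 averaged, Xist in males had -0.11, and 0 lists differed between the sexes. With DESeq2 allelic calls were 14 in morulae, 27 averaged, 14 in females and 15 in males. Count columns as named gave 4 in females and 4 in males with edgeR, and 4 and 4 with TMM, and an X share difference of -13.8 points. Genotype only gave 9, and limma on allelic RPKM 9 averaged and 0 in morulae. With an estimated correlation 0 lists passed in morulae, 1 in females, 1 in males, 1 averaged and 0 between the sexes.

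The candidate list difference in ExE was -1.76 points for summed reads. Paternally expressed imprinted genes in morulae had 2.25 with at least 20 reads, 1.03 for summed reads and 2.64 with allelic RPKM, and maternally expressed ones 6.89 with at least 20 reads. Paternally biased control genes between 25% and 75% in matKO numbered 26 of 148 in morulae and 5 of 77 in ExE at a threshold of 90%, and 56 of 255 in morulae with at least 20 reads.

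Leaving out each library gave lowest and highest counts of 1 and 16 in morulae, 1 and 3 in females, 1 and 6 in males, 3 and 17 averaged and 0 and 1 between the sexes. Allelic counts were 0 and 123 in morulae, 7 and 24 averaged and 22 and 203 in females. Paternally biased control genes between 25% and 75% in matKO were 95 of 350 and 405 of 795 in morulae and 12 of 162 and 25 of 181 in ExE. In morulae log2 changes were -0.33 and 0.58 for Eed and -0.76 and 0.82 for Slc38a4. Those of Tsix were -0.32 and 0.44 in females, -0.020 and 0.17 in males and -0.12 and 0.26 averaged, and those of Xist -0.29 and 0.025, -0.12 and 0.14, and -0.14 and 0.017. The maternally expressed imprinted genes in ExE had -2.44 and -1.51 points. Libraries left alone in a group were assumed to vary like the other groups.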

Other observations

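H19, which is expressed from the maternal allele, had a paternal level of 422 allelic RPKM in matKO female 1, 307 in matKO male 4 and 215 in matKO male 5, against 0.82 to 15.6 in the 4 controls. These libraries and H19 were chosen after their values were seen, and the same 3 libraries had the highest maternal shares of paternally expressed imprinted genes. Its maternal share was 71.6%, 73.0% and 68.4% in these libraries and 97.5% to 99.9% in controls. Igf2, expressed from the paternal allele, had maternal shares of 31.6% in matKO male 4 and 38.8% in matKO male 5, against 20.3% to 24.7% in controls, but 16.2% in matKO female 1, so the 3 libraries did not share a rise of Igf2.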
